A study of Mus musculus with 12 samples.

How the data were processed

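RNA was sequenced from the hippocampus of 12 male C57BL/6 mice aged 8 weeks, 3 independent mice in each of 4 groups, with a stranded mRNA library kit, per the labels' protocols. F0_Ctl were normal mice and F0_Dep were mice with depression induced by stress. F1_Ctl and F1_Dep were male offspring of normal males and of stress-induced depressed males. The labels of the F1_Ctl libraries carry sequencing lane names and those of the other groups do not, so a difference in sequencing between F1_Ctl and the other groups cannot be told apart from the group. How the stress was applied, and when in the day tissue was taken, is not given in the sources used here. The sample titles name no father or litter, so F1 mice of a group may share one.

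The authors deposited a table of expected counts (estimated counts that need not be whole) for 35812 Ensembl gene IDs in all 12 libraries. The counting tool and annotation behind that table are not given in the sources used here, nor is whether strand was used, so reads of overlapping genes and antisense partners cannot be told apart. The authors also deposited FPKM values per gene for 9 libraries, those of F0_Ctl, F0_Dep and F1_Dep. HISAT2, Cufflinks 2.2.1 and the mouse build mm10 are named, without their roles, per the submitters' processing notes. FPKM values of F1_Ctl were not used here. The library totals of the count table ran from 18277208 to 23083678.

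Gene symbols were matched by Ensembl ID, which gave a symbol for 35202 IDs and none for 610; IDs without a symbol held 0.579% of the counts. A further 37 IDs were summed into another of the same symbol, and 1 short noncoding gene was left out. Of 26305 gene positions listed with the FPKM values, 99.92% overlapped the same gene in GENCODE M21 on GRCm38, and coordinates are given on that build. The number of per-sample columns left unused was 0.

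The expected counts were rounded to whole numbers and tested with edgeR 4.0.16 under R 4.3.3. Libraries were scaled by TMM, genes with low counts were removed by filterByExpr, and 16163 genes were fitted with the quasi-likelihood F-test over all 4 groups together. A gene was called changed at a Benjamini-Hochberg adjusted p under 0.05. Standard errors of log2 fold changes were derived from the fold change and its F statistic and are approximate. The test fixed before the data were examined was limma on FPKM with the count test to be used if counts were given for all groups, so the count test is the one reported. For the same reason the naming rule's minimum of a mean FPKM of 2 became a mean of 2 CPM (counts scaled to library size). Where a gene's FPKM values are given beside its counts, they were tested with limma 3.58.1 on log2(FPKM + 1) after keeping genes with an FPKM of at least 1 in at least 3 libraries, and their fold changes are on that log scale, which understates the change of low genes.

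Genes were named by a rule fixed before the data were examined. It takes per comparison the 8 largest rises and 8 largest falls past the threshold whose 3 libraries of one group all lie on one side of the other's, up to 2 more members of a list that passed or that held several called genes, and 12 stress, activity and cell type genes in every comparison. Predicted genes and pseudogenes were counted but passed over, and some genes the rule took are not reported here. Where fewer than 5 genes passed, the 4 with the smallest p in each direction were given as not passing.

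A set of 38 gene lists, fixed before the data were examined, covered the stress response, neurons and synapses, cell types of the hippocampus and of neighbouring tissue, and core metabolism. Each was tested with camera at a preset correlation of 0.01 on log2 CPM with a prior count of 2, adjusted over the lists. Camera was repeated with an estimated correlation, under which no list passed in any comparison, and with fry, which tests whether the genes of a list move one way on balance. A list's level in a library is the median over its members of the log2 CPM centred on the mean of all 12 libraries. The number of members past the threshold adjusted over the list alone is given beside the number over all genes.

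Comparisons were F0_Dep with F0_Ctl, F1_Dep with F1_Ctl, F1_Dep with F0_Ctl, F1_Dep with F0_Dep, F1_Ctl with F0_Ctl, and the interaction, the difference between the F1 and the F0 change. Fold changes of comparisons with shared F0_Ctl libraries were set beside 100 simulations of unchanged groups. The test was checked on simulated counts for F0_Dep against F0_Ctl over 15975 genes. It recovered 5.97% of genes changed by 0.5 on the log2 scale, 68.7% of those changed by 1 and 95.5% of those changed by 2. Of its 118 calls, 5 fell on unchanged genes. Both kinds of simulation drew each gene independently and held no difference between libraries shared by many genes, which the real libraries showed. The share of false calls therefore need not hold for the real data.

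Alternatives comprised DESeq2 1.42.0, other scalings, filters and variance models, voom with library weights, the FPKM values, fits to the compared groups alone, the replicate number as a block, other thresholds, and each library left out in turn. Where the number of alternatives in which a gene passed is given, the alternative with the looser threshold is judged at an adjusted p under 0.1. Others were chosen after seeing the data. They took the choroid plexus level as a covariate, left out 3 libraries with the most choroid plexus or striatal transcript, or kept genes whose counts and FPKM values moved together.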

Results

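Hippocampal RNA of 12 male mice aged 8 weeks was compared in 4 groups of 3 mice: normal mice (F0_Ctl), mice with depression induced by stress (F0_Dep), sons of normal males (F1_Ctl) and sons of stress-induced depressed males (F1_Dep). Library totals of the deposited expected counts lay between 18277208 and 23083678. Mitochondrially encoded genes took 8.26 ± 0.86% of the counts in F0_Ctl, 5.17 ± 0.12% in F0_Dep, 9.2 ± 1.7% in F1_Ctl and 6.96 ± 0.24% in F1_Dep (mean and SD, n = 3). The F0_Dep share leaves out counts in 2 pseudogenes, Gm28661, a nuclear copy of mt-Co2, and Gm28437. Gm28661 held 4343 ± 284 CPM in F0_Dep and 0 in the other groups, so part of this difference may come from how reads were assigned. Tissue markers also differed between single libraries. The median level of choroid plexus markers, which come from the fluid-secreting tissue beside the hippocampus, was 2.62 above the mean of all libraries on the log2 scale in F0_Ctl 3 and 3.63 above it in F1_Ctl 3. It was 2.26 ± 0.53 in F1_Dep and -1.6 ± 0.94 in F0_Dep (SD, n = 3).

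**Figure D1:**
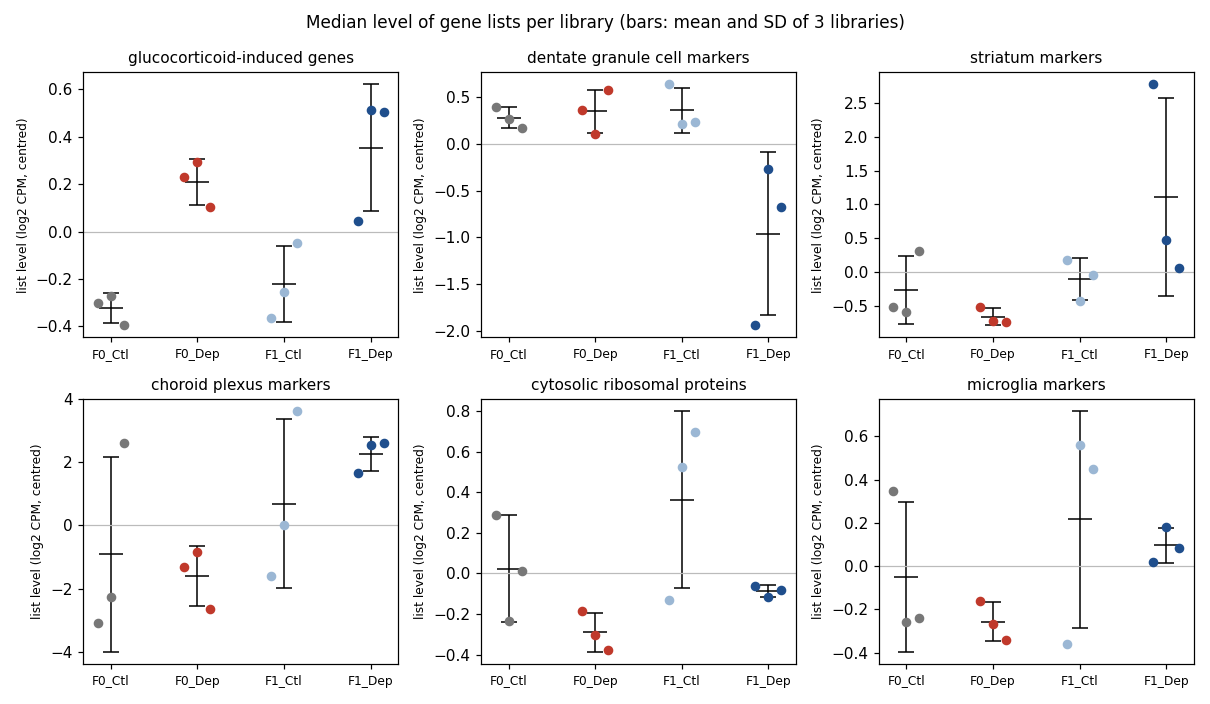
Median level of 6 gene lists in each library, as log2 CPM centred on the mean of the 12 libraries, with the mean and SD of the 3 libraries of each group as bars. The glucocorticoid list stood above 0 in the libraries of F0_Dep and F1_Dep, the dentate list lay lowest at -1.94 in F1_Dep 1, and the striatum list stood highest at 2.78 in the same library.

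The comparison of F0_Dep with F0_Ctl asks how the hippocampus of stressed mice differed from that of normal mice. Genes induced by glucocorticoids, the stress hormones of the adrenal cortex, stood higher in F0_Dep in 19 of 21 measured members, with a median log2 fold change of 0.45. Of these, Plin4, a coat protein of lipid droplets, rose by 2.64 ± 0.39 (log2 ± SE) from 3.28 ± 1.37 to 20.5 ± 5.14 CPM (SD, n = 3), and Cdkn1a, an inhibitor of cyclin-dependent kinases, rose by 0.90 ± 0.17. Both also rose in FPKM, by 1.11 ± 0.18 and 0.68 ± 0.16. Both are protein-coding genes on chromosome 17 of GRCm38, Plin4 (ENSMUSG00000002831) at 56100591 to 56109803 and Cdkn1a (ENSMUSG00000023067) at 29090976 to 29100727. Plin4 missed the threshold without F0_Ctl 1, F0_Dep 2 or F0_Dep 3, with adjusted p of 0.0896, 0.151 and 0.147, and Cdkn1a passed, of the 6 omissions, without F0_Ctl 3 alone. Adjusted over the list alone, 15 members passed. The list had a camera adjusted p = 1.95e-09, an adjusted p = 0.726 with an estimated correlation, and a fry adjusted p = 0.0318. Sgk1, a kinase in this list (chromosome 10, 21882184 to 21999903), had a log2 fold change of 0.96 ± 0.25 with an adjusted p = 0.0836, and Fkbp5, a co-chaperone of the glucocorticoid receptor, one of 0.49 ± 0.12 with an adjusted p = 0.078. Neither passed in the edgeR test, while Sgk1 passed in FPKM with an adjusted p = 0.0158 and in 10 of 28 alternatives in all, with adjusted p from 0.00298 to 0.264, and Fkbp5 in 3 of 28, from 0.00861 to 0.298. For both genes these passes include that by the looser threshold of 0.1.

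Over all genes, 80 of 16163 passed in F0_Dep against F0_Ctl, 56 higher and 24 lower; without TMM scaling 18 were higher and 24 lower. Etnppl, an enzyme that breaks down phosphoethanolamine, rose by 1.68 ± 0.22, from 10.9 ± 1.34 to 34.9 ± 2.34 CPM (SD, n = 3), and by 1.48 ± 0.12 in FPKM. It missed the threshold without F0_Dep 3 alone, with an adjusted p = 0.0729. The inducible heat shock protein gene Hspa1b rose by 1.9 ± 0.33, and is uncertain, because its near-identical neighbour Hspa1a can share its reads. Slc9a7, Klhl11, Palm2 and Lonrf3 rose by 1.42, 1.4, 1.29 and 1.23. Among synapse genes, Dlgap2 rose by 0.89 ± 0.17 and Cacng2, a subunit of AMPA receptors, by 0.65 ± 0.12. Lower in F0_Dep were the growth factor gene Ptn at -0.75 ± 0.12, the tubulin gene Tubb2b at -0.73 ± 0.11, Tm7sf2, an enzyme of sterol synthesis, at -0.79 ± 0.13, Lims2 at -0.82 ± 0.16, and the vessel genes Itm2a at -0.65 ± 0.11 and Rgs5 at -0.48 ± 0.09, which in FPKM had an adjusted p = 0.262. Of the 75 called genes with an FPKM value, 72 had the same sign there and 59 were called in both. Of the 21 genes called in counts that the naming rule took, 2 kept the call in each omission of 1 library, Lrrc17 and mt-Co2.

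**Figure D2:**
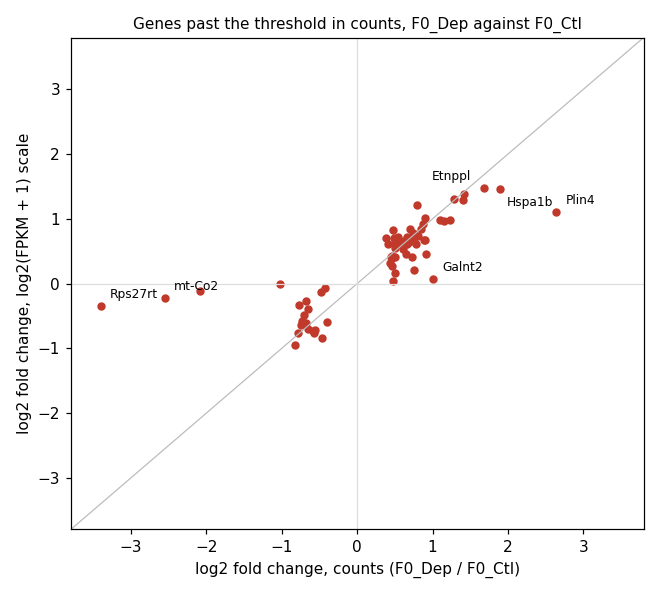
Log2 fold change of F0_Dep over F0_Ctl in counts (horizontal) and on the log2(FPKM + 1) scale (vertical) for called genes with both values. The grey diagonal marks equal change. The sign is the same for 72 of the 75 such genes. The genes of opposite sign, Gm28661, Gm28437 and Rpl36a-ps2, lie outside the plotted range. They had 19.4, 18.1 and -9.46 in counts against -0.17, -0.29 and 0.57 in FPKM. Among the points shown, Rps27rt and mt-Co2 lie far from the diagonal, at -3.4 and -2.55 in counts against -0.34 and -0.22 in FPKM.

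Several of the largest changes of F0_Dep in counts were uncertain. The mitochondrial gene mt-Co2 (chromosome M, 7013 to 7696) fell by 2.55 on the log2 scale in counts, from 7980 ± 1360 to 1360 ± 422 CPM (SD, n = 3), but its FPKM changed by -0.22 ± 0.11 with an adjusted p = 0.163. Its nuclear copy Gm28661, chosen after its values were seen (chromosome 1, 24614885 to 24615565, an unprocessed pseudogene), matches it over 681 of 681 aligned bases. Gm28661 held 4343 ± 284 CPM in F0_Dep and 0 counts in the other 9 libraries, but its FPKM changed by -0.17 ± 0.11 with an adjusted p = 0.293. Another pseudogene, Gm28437 (chromosome 1, 24613189 to 24613971), held 1450, 1400 and 2300 CPM in F0_Dep 1 to 3 and at most 0.09 elsewhere. The FPKM of Gm28437 changed by -0.29 ± 0.12. Rps27rt, a gene copy related to Rps27, had -3.4 ± 0.49 in counts and -0.34 ± 0.17 in FPKM. Lrrc17 had 2.92 ± 0.23 in counts, lay below the FPKM filter, and had -0.05 in FPKM without that filter. The mitochondrial gene mt-Nd6 fell by 0.77 on the log2 scale in counts and by 0.33 in FPKM.

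In 38 lists, 17 passed camera in F0_Dep against F0_Ctl. Genes of presynaptic vesicle release stood higher in 21 of 24 members with a median of 0.26, and postsynaptic density genes in 19 of 25 with a median of 0.26, where Dlgap2 and Cacng2 rose. Their adjusted p was 1.29e-06 and 0.000123, and each had an adjusted p = 0.726 with an estimated correlation. Cytosolic ribosomal protein genes stood lower in 80 of 81 members with a median of -0.33, none of them past the threshold, with an adjusted p = 1.95e-09 and an adjusted p = 0.763 with an estimated correlation; their median was -0.175 without F0_Ctl 1 (adjusted p = 0.000678). Mitochondrially encoded genes stood lower in 12 of 13 with a median of -0.56, and mt-Nd6 fell. The fall of mt-Co2 in counts is uncertain, as given above, and the other 12 had a median of -0.52. Whether any of those 12 lost reads to Gm28437 was not tested. This list had an adjusted p = 4.11e-06, an adjusted p = 0.726 with an estimated correlation, and no pass in FPKM with an adjusted p = 0.156. Nr3c1 and Nr3c2, the corticosteroid receptor genes, had log2 fold changes of -0.08 ± 0.17 and 0.06 ± 0.16, and Bdnf, Crhr1, Arc, Egr1, Fos, Gfap and Aif1 had -0.02, -0.37, -0.29, -0.69, -0.57, -0.05 and -0.48, none past the threshold. Ttr, the main choroid plexus transcript, had 1550 ± 2670 CPM in F0_Ctl, where F0_Ctl 3 held 4630, and 105 ± 95.6 in F0_Dep (SD, n = 3). Its log2 fold change was -3.89 ± 2.2 in counts with an adjusted p = 0.359 and 0.13 ± 2.3 in FPKM. The list of choroid plexus markers had a median of -2.77 and did not pass, with an adjusted p = 0.536, but passed as lower without F0_Ctl 1 (adjusted p = 0.0123) and as higher without F0_Ctl 3 (adjusted p = 0.00906). The count of 80 genes became 7 without F0_Ctl 1, 373 without F0_Ctl 2, 17 without F0_Dep 1, 11 without F0_Dep 2 and 5 without F0_Dep 3. It was 512 without F0_Ctl 3, F1_Ctl 3 and F1_Dep 1 together, a choice made after seeing the data, and 23 when these 2 groups alone were fitted.

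The comparison of F1_Dep with F1_Ctl asks whether sons of depressed males differed from sons of normal males; sequencing lanes are named for F1_Ctl alone, so a batch could not be told apart from the group. The glucocorticoid-induced genes stood higher in F1_Dep in 19 of 21 members, with a median of 0.62. Plin4 rose by 2.47 ± 0.38, from 4.79 ± 2.28 to 26.5 ± 8.07 CPM (SD, n = 3), Cdkn1a by 1.09 ± 0.17, and the clock gene Per1 by 0.80 ± 0.13. Plin4 missed the threshold without F1_Ctl 2, F1_Dep 2 or F1_Dep 3, with adjusted p of 0.166, 0.0607 and 0.137. Adjusted over the list alone, 13 passed. The list had an adjusted p = 4.25e-12 by camera and an adjusted p = 0.526 with an estimated correlation, and missed the threshold by fry with 0.0523. Sgk1 had 1.34 ± 0.25 with an adjusted p = 0.0602, and Fkbp5 had 0.03 ± 0.12. Sgk1 passed in 10 of 23 alternatives, where its adjusted p ran from 1.66e-05 by DESeq2 to 0.188, among them those without F1_Ctl 1 and F1_Ctl 3, with adjusted p of 0.0383 and 0.0267. Without F1_Dep 1 the median of the list was 0.72.

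Dentate granule cell markers, genes of the principal neurons of the dentate gyrus, stood lower in F1_Dep in 9 of 11 members with a median of -1.34, and 8 passed adjusted over the list alone. Of these, Tdo2, a tryptophan-degrading enzyme (ENSMUSG00000028011, chromosome 3, 81957090 to 81976202), fell by 1.84 on the log2 scale (SE 0.3), from 10.6 ± 1.19 to 2.95 ± 1.22 CPM, and Plk5 fell by 1.41 (SE 0.21), from 47.1 ± 5.84 to 17.7 ± 5.89 (SD, n = 3). The list had an adjusted p = 5.4e-08 and an adjusted p = 0.526 with an estimated correlation. Outside the list, Synpr, a synaptic vesicle protein gene (ENSMUSG00000056296, chromosome 14, 13284780 to 13616340), fell by 1.34 (SE 0.16), from 172 ± 12 to 67.9 ± 17.4 CPM. Synpr missed the threshold without F1_Ctl 2 or F1_Dep 3, with adjusted p of 0.111 and 0.121. The genes Fabp7, Lingo2, Myoc, Htra4 and Cdhr1 had -1.4, -1.35, -2.08, -1.91 and -1.53. Striatum markers stood higher in 11 of 11 members with a median of 1.61, an adjusted p = 4.63e-05 and an adjusted p = 0.582 with an estimated correlation. Their level was 2.78 in F1_Dep 1, 0.48 in F1_Dep 2 and 0.06 in F1_Dep 3. Without F1_Dep 1 their median was 0.37, while that of the dentate list was -0.95, and the lists still passed camera with adjusted p of 0.0209 and 7.86e-11.

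**Figure D3:**
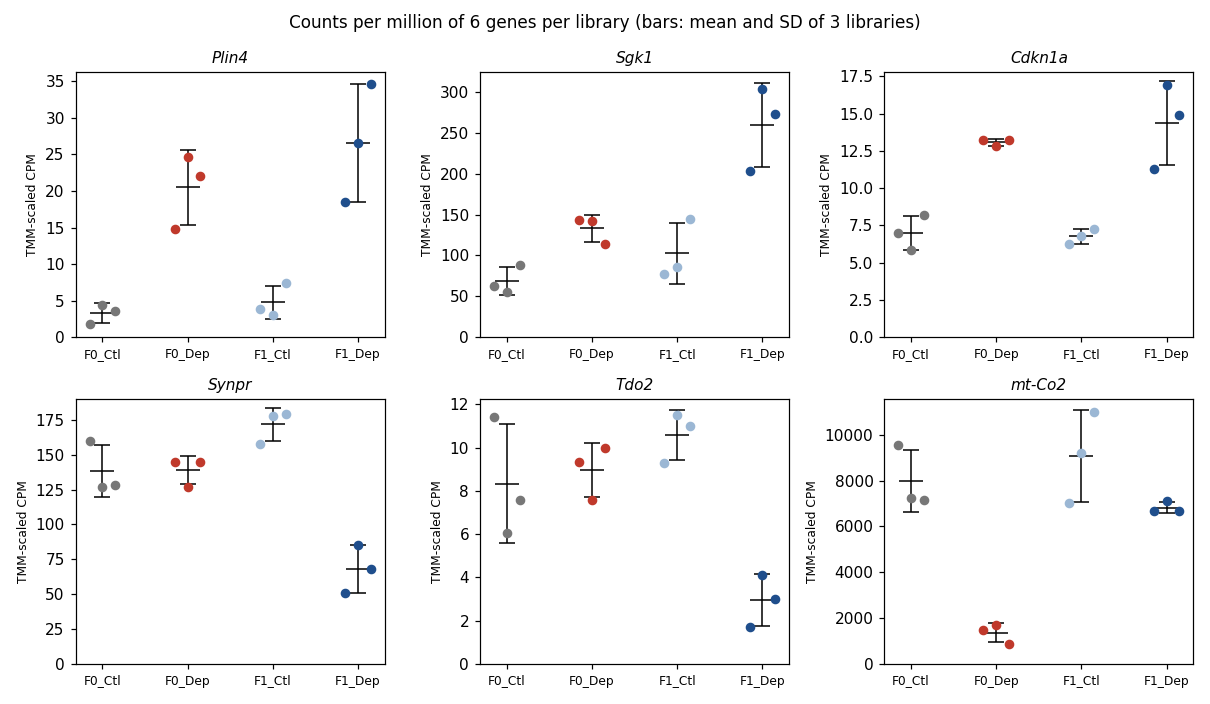
TMM-scaled CPM of 6 genes in each library, with the mean and SD of 3 libraries as bars. Plin4 lies between 14.8 and 34.6 in the libraries of F0_Dep and F1_Dep and at most at 7.38 in the control libraries, Synpr and Tdo2 are lowest in F1_Dep, and mt-Co2 is lowest in F0_Dep, the group in which its nuclear copy Gm28661 held counts.

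Of 16163 genes, 27 passed in F1_Dep against F1_Ctl, 7 higher and 20 lower; without TMM scaling 9 were higher and 13 lower. Without F1_Dep 1, 13 were higher and 8 lower. None of the 15 named genes called kept the call in each omission of 1 library. The other genes that rose were Krt80 by 2.41 ± 0.34, Plk3 by 0.94 ± 0.12, the collagen-modifying enzyme gene P4ha2 by 0.90 ± 0.14, and Vgf, a neuropeptide precursor, by 0.66 ± 0.11. Cytosolic ribosomal protein genes stood lower in 81 of 81 members with a median of -0.49 and 58 past the threshold adjusted over the list alone, though none over all genes. Their adjusted p was 4.14e-22, with an adjusted p = 0.582 with an estimated correlation. Their levels in the F1_Ctl libraries were -0.13, 0.53 and 0.70, and lay between -0.12 and -0.06 in F1_Dep, and their median was -0.303 without F1_Ctl 3. Immediate early genes, which follow neuronal activity, stood higher in 20 of 24 with a median of 0.50, none of them past the threshold over all genes, with an adjusted p = 5.53e-05 and an adjusted p = 0.587 with an estimated correlation. Arc, Egr1 and Fos had 1.35 ± 0.41, 1.39 ± 0.38 and 0.90 ± 0.44, with adjusted p of 0.169, 0.132 and 0.365. Egr1 passed in 4 of 23 alternatives, with adjusted p from 0.0229 to 0.326, and Arc and Fos in none. Endoplasmic reticulum stress genes and heat shock chaperones had medians of 0.27 and 0.19, adjusted p of 4.77e-07 and 1.1e-06, and each an adjusted p = 0.526 with an estimated correlation. Nr3c1, Nr3c2, Bdnf, Crhr1, Gfap, Aif1 and Ttr had 0.04, -0.25, -0.40, 0.24, -0.39, -0.37 and 0.23, none past the threshold. The count of 27 genes became 678 without F1_Ctl 1, 0 without F1_Ctl 2, 15 without F1_Dep 2 and 0 without F1_Dep 3. It was 0 when these 2 groups alone were fitted and 339 without F0_Ctl 3, F1_Ctl 3 and F1_Dep 1 together, 252 higher and 87 lower. With those libraries left out, choroid plexus levels were 2.54 and 2.6 in F1_Dep against -1.59 and 0.017 in F1_Ctl. The count of 339 therefore cannot be told apart from a difference in choroid plexus content.

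F1_Dep was also compared with F0_Ctl, the unexposed mice of the earlier generation, from which they differ in generation as well as in paternal history. No gene passed in the edgeR test, 2078 genes had an unadjusted p under 0.05 against 808 by chance, and DESeq2 called 408 genes, voom with library weights 20 and limma on FPKM 37. The smallest adjusted p was 0.0526, held by Plin4 at 3.01 ± 0.39 and by Sgk1 at 1.92 ± 0.25, which went from 68.4 ± 17.2 to 260 ± 51.2 CPM (SD, n = 3). Krt80 and Arl4d had 2.14 ± 0.34 and 1.12 ± 0.16, and Plk5, Pla2g4e, Lrrtm4 and the cell death gene Bbc3 had -1.36, -1.49, -0.96 and -0.89, each with an adjusted p = 0.0743. In FPKM, Plin4, Sgk1, Plk5 and Bbc3 passed, with adjusted p of 0.0225, 0.0215, 0.0225 and 0.0225, while in counts Plin4, Sgk1, Arl4d and Pla2g4e passed without F1_Dep 1, with adjusted p of 0.0242, 0.0242, 0.0299 and 0.0358, Sgk1 without F0_Ctl 3 with 0.0235 and Plk5 without F1_Dep 2 with 0.0261. The glucocorticoid list stood higher in 20 of 21 members with a median of 0.76 in counts and 0.52 in FPKM. It had an adjusted p = 5.64e-15, an adjusted p = 0.169 with an estimated correlation and a fry adjusted p = 0.0131. Dentate granule markers stood lower in 11 of 11 with a median of -1.19 in counts and -1.09 in FPKM, an adjusted p = 1.41e-08 and an adjusted p = 0.203 with an estimated correlation, and had -0.783 without F1_Dep 1. Myelin genes stood higher in 20 of 20 with a median of 0.56, an adjusted p = 1.15e-09 and an adjusted p = 0.513 with an estimated correlation, and choroid plexus markers in 19 of 19 with a median of 1.17, an adjusted p = 1.41e-08 and an adjusted p = 0.513 with an estimated correlation. Both medians moved with single F0_Ctl libraries, though both lists still passed camera without them. The myelin median was 0.311 without F0_Ctl 1 and 0.918 without F0_Ctl 3, whose level of 0.49 lay above 0.42 and 0.46 in F1_Dep 2 and F1_Dep 3. The choroid plexus median was 0.684, 0.674 and 5.3 without F0_Ctl 1, 2 and 3, and F0_Ctl 3 stood above each F1_Dep library, at 2.62 against at most 2.6. The genes Fkbp5, Nr3c1, Nr3c2, Crhr1, Bdnf, Fos, Arc, Egr1, Ttr, Gfap and Aif1 had log2 fold changes of 0.06, 0.09, -0.24, -0.13, -0.27, 0.92, 0.8, 0.75, 1.17, 0.15 and 0.195, none past the threshold. Without F1_Dep 1 the count of genes was 12, without F0_Ctl 3 it was 4, and without F0_Ctl 2 or F1_Dep 2 it was 1. It was 629 without F0_Ctl 3, F1_Ctl 3 and F1_Dep 1 together. That omission left choroid plexus levels of 2.54 and 2.6 in F1_Dep against -3.1 and -2.25 in F0_Ctl. A difference in choroid plexus content therefore cannot be told apart from the group in this count.

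Fold changes of F0_Dep and F1_Dep against the shared F0_Ctl libraries correlated across genes with r = 0.131 and rho = 0.235, where genes are not independent replicates, and unchanged groups simulated against the same controls gave a mean r of 0.498. The covariance was 0.0268 against 0.053 in the simulations, and 61.4% of genes had the same sign against 66.7%. The 3 control libraries were too few to be split. Without F0_Ctl 3 the correlation was 0.392 and without F0_Ctl 2 it was 0.265. Against their own controls the fold changes of F0_Dep and F1_Dep correlated across genes with Pearson's r = -0.0406 and Spearman's rho = 0.0799, and 56.1% of genes had the same sign, where simulations of unchanged groups gave a mean r of 0.000125 and 50%. Pearson's r turned to 0.0294 without F0_Ctl 3, 0.0416 without F1_Ctl 1 and 0.036 without F1_Ctl 2, and became -0.131 without F0_Ctl 1 and -0.167 without F1_Ctl 3. Plin4 and Cdkn1a were called higher in both of these comparisons, where independent lists would share 0.024 genes, and no gene was called lower in both.

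Sons and stressed mice themselves, F1_Dep and F0_Dep, differed in 465 genes, 212 higher and 253 lower in F1_Dep; without TMM scaling 245 were higher and 185 lower. Myelin genes stood higher in 20 of 20 members with a median of 1.16, and 8 rose over all genes and 19 adjusted over the list alone. Sox10, a transcription factor of oligodendrocytes, rose by 1.17 ± 0.2, and Ugt8a, a galactolipid enzyme of myelin, by 1.62 ± 0.31, from 37.3 ± 4.22 in F0_Dep to 115 ± 20.5 CPM in F1_Dep (SD, n = 3). The list had an adjusted p = 3.03e-13 and an adjusted p = 0.621 with an estimated correlation. Of the oligodendrocyte precursor markers, Olig1 and Olig2 rose by 0.92 ± 0.18 and 1.15 ± 0.2; the list had an adjusted p = 0.00182 and an adjusted p = 0.485 with an estimated correlation. Dentate granule markers stood lower in 11 of 11 with a median of -1.28, where Tdo2 and Plk5 fell by 1.6 and 1.34 on the log2 scale, with an adjusted p = 2.01e-06 and an adjusted p = 0.621 with an estimated correlation. Of adult neurogenesis markers, Bhlhe22 was lower at -1.01 ± 0.2 and Stmn1 higher at 0.97 ± 0.16; the list had an adjusted p = 0.0221 and an adjusted p = 0.621 with an estimated correlation. It missed the threshold without F0_Dep 1 (adjusted p = 0.0613), without F1_Dep 3 (adjusted p = 0.061) and in FPKM (adjusted p = 0.161).

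The striatal gene Adora2a, an adenosine receptor, rose in F1_Dep over F0_Dep by 4.13 ± 0.92, and the striatum list had a median of 2.23, or 1.02 without F1_Dep 1, an adjusted p = 4.48e-06 and an adjusted p = 0.621 with an estimated correlation. Adora2a had 21.8 ± 28.4 CPM in F1_Dep (SD, n = 3), a spread set by F1_Dep 1 at 54.6 against 7.1 and 3.87 in F1_Dep 2 and F1_Dep 3. Over the alternatives its log2 fold change ran from 2.13 to 4.63. Choroid plexus markers had a median of 3.86, an adjusted p = 7.2e-07 and an adjusted p = 0.621 with an estimated correlation, and Ttr had 5.05 ± 2.3 with an adjusted p = 0.229. Klk6, Trbc2, Rxrg, Krt80 and Nxph3 rose by 3.07, 3.3, 3.92, 2.89 and 2.89. Of these, Rxrg held 23 CPM in F1_Dep 1 against 2.32 and 2.43 in F1_Dep 2 and F1_Dep 3, and without F1_Dep 1 Klk6, Trbc2, Rxrg and Nxph3 did not pass, at 2.69, 2.67, 1.97 and 2.3. The genes Ttn, Cdhr1, Fat4, Olfm4, Myoc and Nkain3 had -2.37, -1.78, -1.64, -1.58, -1.58 and -1.55. The immediate early gene Jun was lower at -1.16 ± 0.22, whereas Egr1, Fos and Arc had 1.44, 1.49 and 1.09 and did not pass in the edgeR test. They passed in FPKM with adjusted p of 0.0269, 0.0147 and 0.0472, and in 11, 10 and 7 of 28 alternatives in all. Lrrc17, Rps27rt and mt-Co2 had -2.08, 3.07 and 2.33 in counts with the uncertainty given above, and mt-Atp8 was lower at -0.67 ± 0.13, with -1.35 ± 0.16 in FPKM. The short gene mt-Atp8 lies beside mt-Co2, at 7766 to 7969 on chromosome M, and FPKM of very short genes can be unstable. It held 118, 139 and 133 CPM in F0_Dep 1 to 3, against 104, 91.1 and 75.4 in F0_Ctl 1 to 3. Whether its reads were assigned differently in F0_Dep was not tested. Grm3 and Grm8, glutamate receptor genes, rose by 1.02 ± 0.19 and 1.85 ± 0.43. Camk2b was lower at -0.60 ± 0.12 and Dlg1 higher at 0.66 ± 0.14. Cryab and Hspa8, chaperone genes, rose by 1.32 and 0.38, the sterol gene Cyp51 by 0.39, and the lysosomal gene Npc1 by 0.52. Adora2a, Rxrg, Grm8 and Cyp51 did not pass in FPKM, with adjusted p of 0.0628, 0.0991, 0.0555 and 0.0652. Of the 35 genes called in counts that the naming rule took, 17 lost the call in all 6 omissions of 1 library, and 2 kept it in each, Lrrc17 and mt-Co2. Fkbp5 and Sgk1 had -0.43 ± 0.12 and 0.97 ± 0.25 with adjusted p of 0.0743 and 0.0536, and Sgk1 passed in FPKM with an adjusted p = 0.0326 and in 12 of 28 alternatives in all, with adjusted p from 0.000543 to 0.364, and Fkbp5 in 4 of 28, from 0.00516 to 0.468. Nr3c1, Nr3c2, Crhr1, Bdnf, Gfap and Aif1 had 0.17, -0.29, 0.24, -0.25, 0.198 and 0.68, none past the threshold. Of the 426 called genes with an FPKM value, 422 had the same sign there and 374 were called in both. The count of 465 genes became 25, 16 and 8 without F0_Dep 1, F0_Dep 2 and F0_Dep 3, and 13, 172 and 14 without F1_Dep 1, F1_Dep 2 and F1_Dep 3. It was 8 with the choroid plexus level as a covariate, 1347 without F0_Ctl 3, F1_Ctl 3 and F1_Dep 1 together, 823 higher and 524 lower, and 3746 when these 2 groups alone were fitted.

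The control groups of both generations, F1_Ctl and F0_Ctl, differed in no gene in the edgeR test, with 957 genes at an unadjusted p under 0.05 against 808 by chance, and in 0 genes by DESeq2 and by voom with library weights. The genes with the smallest p were Efemp1, Zc3hav1, Kctd4 and Hibch, at 0.82, 0.80, 0.67 and 0.43, and Cdc25b, Clcn2, Ccdc84 and Styx, at -0.83, -0.58, -0.53 and -0.46, each with an adjusted p = 0.75. Cytosolic ribosomal protein genes stood higher in F1_Ctl in 79 of 81 members with a median of 0.38, an adjusted p = 8.76e-19 and an adjusted p = 0.654 with an estimated correlation, and nuclear genes of oxidative phosphorylation in 74 of 78 with a median of 0.26, an adjusted p = 1.34e-12 and an adjusted p = 0.654 with an estimated correlation. The ribosomal median was 0.589 without F1_Ctl 1 and 0.187 without F1_Ctl 3. That of oxidative phosphorylation was 0.156 without F0_Ctl 2, and 0.43, 0.166 and 0.13 without F1_Ctl 1, 2 and 3, and F1_Ctl 1 lay at -0.10, below F0_Ctl 1 at 0.19 and F0_Ctl 3 at 0.05. Glucocorticoid-induced genes and dentate granule cell markers did not pass, with medians of 0.13 and 0.15, though the former passed without F1_Ctl 2 (adjusted p = 0.0467). The genes Fkbp5, Sgk1, Nr3c1, Nr3c2, Crhr1, Bdnf, Fos, Arc, Egr1, Ttr, Gfap and Aif1 had log2 fold changes of 0.04, 0.58, 0.05, 0.00842, -0.37, 0.125, 0.02, -0.55, -0.64, 0.94, 0.54 and 0.56, none past the threshold. Without F1_Ctl 1, Efemp1, Zc3hav1, Cdc25b, Clcn2, Ccdc84, Styx and Gfap passed, with adjusted p of 0.0209, 0.0405, 0.0346, 0.0361, 0.0333, 0.0195 and 0.0479. Without F1_Ctl 1 the count of genes was 400 and without F0_Ctl 3 it was 9, and it was 23 without F0_Ctl 3, F1_Ctl 3 and F1_Dep 1 together.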

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

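The tests in this part on the count table, the mitochondrial copy, and dentate and striatal tissue were chosen after their results were seen. Those on choroid plexus content, whose covariate was chosen after seeing the data, and on time of day were chosen after the glucocorticoid result was seen but before their own values were, and those on other splits of the libraries were planned.

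The change of F1_Dep against F1_Ctl differed from that of F0_Dep against F0_Ctl in 11 genes by the interaction term. Krt80, mt-Co2, Plk3 and Vgf had differences of 3.16, 2.14, 1.49 and 1.07 on the log2 scale, and Lrrc17, Sema5a, Kctd4, Adarb2, Lyst, Galnt2 and Unc5d had -2.92, -1.62, -1.56, -1.56, -1.43, -1.21 and -1.21. Without TMM scaling 3 genes were higher and 3 lower, against 4 and 7. None of the 11 kept the call in each omission of 1 library. The genes Fkbp5, Sgk1, Nr3c1, Nr3c2, Crhr1, Bdnf, Fos, Arc, Egr1, Ttr, Gfap and Aif1 had -0.46, 0.38, 0.12, -0.30, 0.61, -0.38, 1.47, 1.64, 2.08, 4.12, -0.345 and 0.11, none past the threshold. Egr1 passed in 3 of 28 alternatives, among them that without F0_Ctl 3 with an adjusted p = 0.00839. Both mt-Co2 and Lrrc17 are uncertain in the F0_Dep counts, and Galnt2 changed in F0_Dep by 1.01 in counts against 0.07 in FPKM. Camera called 19 lists in the interaction, among them dentate granule markers with a median of -1.39, striatum markers with 2.27 and myelin genes with 0.74, each with an adjusted p = 0.804 with an estimated correlation. The striatum median was 0.996 without F1_Dep 1 and the myelin median 0.337 without F0_Ctl 3. The glucocorticoid list did not pass, with a median of -0.00232, opposite in sign to its test, and a camera adjusted p of 0.799. Of 100 splits drawn, 1 gave as many genes, the real one with 11, and the highest other gave 3, but regrouping within a generation puts the changes called there into the spread of the other splits, so these splits do not show whether chance gives this count. The count was 3, 7 and 184 without F0_Ctl 1, 2 and 3, 0, 3 and 1 without F0_Dep 1, 2 and 3, 36, 0 and 126 without F1_Ctl 1, 2 and 3, and 2, 17 and 2 without F1_Dep 1, 2 and 3. It was 487 without F0_Ctl 3, F1_Ctl 3 and F1_Dep 1 together, an omission after which choroid plexus levels parted F1_Dep from F1_Ctl.

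For each comparison of 3 libraries with 3 there are 10 splits, too few for a share under 0.05. Where genes were called, every other split mixes the real groups. Changes between those groups then enter its spread and can lower its count. The splits therefore do not show whether chance gives the real counts. F0_Dep against F0_Ctl gave 80 genes and the highest other split 1, F1_Dep against F1_Ctl 27 and 1, and F1_Dep against F0_Dep 465 and 0; in each, 1 of the 10 splits reached the real count, the real one itself. F1_Dep against F0_Ctl gave 0 genes, which all 10 splits reached because no count can be lower, and the highest other gave 1. F1_Ctl against F0_Ctl gave 0 genes, reached by all 10 splits, but the split of F0_Ctl 1, F1_Ctl 2 and F1_Ctl 3 from F0_Ctl 2, F0_Ctl 3 and F1_Ctl 1 gave 1488 and that of F0_Ctl 1, F0_Ctl 2 and F1_Ctl 1 from the rest 633. These 2 splits mix the generations, so the control libraries also differ in ways that do not follow generation. The split with 1488 genes parted ribosomal levels, at 0.29, 0.53 and 0.70 against -0.24, 0.01 and -0.13. That with 633 parted choroid plexus levels, at -3.1, -2.25 and -1.59 against 2.62, 0.017 and 3.63. Whether tissue content accounts for either count was not tested.

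The counts of mt-Co2 fell by 2.55 on the log2 scale in F0_Dep while Gm28661 held 4343 CPM there and 0 counts elsewhere, though its FPKM changed by -0.172. A fall of mt-Co2 RNA as the whole cause is argued against by the FPKM change of -0.219 ± 0.11. A smaller fall stays open, since the counts of mt-Co2 and Gm28661 summed changed by -0.471 ± 0.14. This lies within the range of the other mitochondrial genes from -1.02 to 0.527, as reads moved between 2 identical sequences would give. A further chromosome 1 pseudogene, Gm28437, held 1450, 1400 and 2300 CPM in F0_Dep 1 to 3 and at most 0.09 elsewhere. Whether another mitochondrial gene lost reads to Gm28437 was not tested, so that range may include such a gene. The number of genes whose count and FPKM changes part by over 1 on the log2 scale was 2.36 times as high for F0_Dep as for F1_Dep (52 against 22 of 12621), so the F0_Dep columns of the count table may have been made differently. Of the called genes, 7 of 75 were among those 52, and how the table was made stays open.

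Dentate granule markers were lower, and striatum markers higher, in F1_Dep than in F1_Ctl. Dilution by tissue from outside as the whole cause of the dentate fall is argued against for F1_Dep 2 and F1_Dep 3. Their CA1 levels were 0.455 and 0.691, against -0.7, -0.023 and -0.157 in F1_Ctl. Over all F1_Dep libraries the CA1 median was 0.578 and the CA2 and CA3 median -0.15, against a dentate upper quartile of -0.929. In F1_Dep 1 the CA1 level was -0.473, so dilution stays open there. CA1 levels also spread widely within a group, with an SD of 1.35 in F0_Ctl. Neocortex marker levels were 0.56, -0.006 and 0.16 in F1_Dep 1 to 3, against 0.13, -0.13 and -0.20 in F1_Ctl. Striatal tissue in the pieces of F1_Dep as a group stays open, since 1 of 11 members (Penk) had all F1_Dep above all F1_Ctl libraries, where chance gives 0.55, but without F1_Dep 1 the list still had a median of 0.367 and passed camera with an adjusted p = 0.0209. All 11 members were highest in F1_Dep 1, where striatal tissue in that piece is a candidate explanation for the striatal rise. It is not one for the whole dentate fall, whose median was -0.952 without F1_Dep 1. Less dentate gyrus in the pieces and lower expression within granule cells of sons of stressed males cannot be told apart, because both give the dentate upper quartile of -0.929.

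Glucocorticoid-induced genes stood higher in F0_Dep and in F1_Dep. An origin in the count table is argued against by FPKM medians against F0_Ctl of 0.753 times those in counts for F0_Dep and 0.677 times for F1_Dep. For F1_Dep against F1_Ctl this could not be checked, because FPKM values of F1_Ctl were not used. An origin in choroid plexus content is argued against by medians with the choroid level as a covariate. These were 1.04 times the original in F0_Dep against F0_Ctl and 0.836 times in F1_Dep against F1_Ctl. Time of day of collection cannot be told apart from the groups: 8 clock genes outside the list had a median of 0.3 in F0_Dep, where Dbp alone was negative at -0.20. Their median was 0.0162 in F1_Dep, over members of both signs, from -0.28 for Dbp to 0.88 ± 0.16 for Per2. Per2 had an adjusted p = 0.0601 in the edgeR test there. A response to stress hormone in stressed mice and their sons stays open as a hypothesis and was not tested.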

How the results depend on the processing

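The choroid plexus covariate, the omission of 3 libraries together and the choice of genes with a stable offset were chosen after seeing the data. Values follow the order F0_Dep against F0_Ctl, F1_Dep against F1_Ctl, F1_Dep against F0_Ctl, F1_Dep against F0_Dep, F1_Ctl against F0_Ctl and the interaction, unless fewer are named; the cause was not tested except where fewer libraries or genes entered. The counts of genes were 80, 27, 0, 465, 0 and 11. They were 688, 167, 14, 1405, 0 and 99 at an adjusted p under 0.1; 1105, 556, 408, 1500, 0 and 498 by DESeq2; 422, 1935, 20, 4703, 0 and 523 by voom with library weights; and 14, 17, 1, 115, 0 and 2 without a mean-variance trend. Without the low-count filter they were 144, 79, 20, 683, 0 and 63. Scaling to library totals without TMM gave 42 in the first and 6 in the interaction, median-of-ratios scaling 2 in F1_Dep against F0_Ctl, and quantile normalization with limma 49 in F1_Dep against F1_Ctl and 8 in F1_Dep against F0_Ctl. Fitting only the groups compared gave 23, 0, 0, 3746 and 0. A minimum of 1.5-fold, robust variance, kept short noncoding genes and separate duplicate symbols left every count within 1.5 times the original.

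On FPKM, which could not be run for F1_Ctl or the interaction, F0_Dep against F0_Ctl, F1_Dep against F0_Ctl and F1_Dep against F0_Dep gave 2929, 37 and 1655 genes; 2917, 37 and 1571 with a pseudocount of 0.1; 2927, 37 and 1635 with 0.5; 1616, 1 and 561 without a filter; and 2821, 27 and 1370 at a mean of at least 5. Alternatives planned for FPKM scaling and variance were run on the counts. The choroid plexus level as a covariate gave 268, 72, 1, 8, 0 and 25, leaving out F0_Ctl 3, F1_Ctl 3 and F1_Dep 1 together gave 512, 339, 629, 1347, 23 and 487, and genes with a stable count-to-FPKM offset gave 210, 33, 0, 575, 0 and 6. Leaving out those libraries kept F1_Dep 2 and F1_Dep 3 at choroid plexus levels of 2.54 and 2.6. The highest level left in the other groups was 0.017 in F1_Ctl 2. Counts that involve F1_Dep there cannot be told apart from choroid plexus content.

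No pairing of the mice by replicate number was seen: correlations of same-numbered libraries ran from -0.18 to 0.5, no pair of groups had all above 0.1, and at most 1 of 3 libraries of a pair of groups correlated best with its own number. With 3 libraries in a group this cannot exclude that a number marks something shared. With the replicate number as a block the counts were 12, 0, 1, 177, 0 and 4, and those of lists 17, 16, 20, 22, 18 and 19.

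Leaving out each library in turn gave 5 to 373, 0 to 678, 0 to 12, 8 to 172, 0 to 400 and 0 to 184 genes, and 14 to 18, 15 to 19, 16 to 22, 17 to 26, 9 to 20 and 14 to 19 lists. Lists past camera numbered 17, 16, 20, 20, 17 and 19; with an estimated correlation 0 in each, by fry 3, 0, 5, 3, 0 and 0, and in FPKM 11 in F0_Dep against F0_Ctl with either pseudocount tried. The correlation with shared controls ran from 0.0678 to 0.392 without single libraries, and was 0.292 in FPKM, 0.236 with a pseudocount of 0.1, 0.289 without a filter and 0.369 at a mean of at least 5. The correlation with own controls ran from -0.167 to 0.0416 and changed sign without F0_Ctl 3 (0.0294), F1_Ctl 1 (0.0416) and F1_Ctl 2 (0.036). Over named genes and alternatives, 3618 values kept direction and side of the threshold, 654 lost the call, 153 gained one, and Lrrc17 in F0_Dep against F0_Ctl turned to -0.0453 in FPKM without a filter. Small changes were seldom detectable: simulated changes of 0.5 on the log2 scale were recovered in 5.97% of genes, and the part of depth in this was not tested, because the simulation did not vary it.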

Other observations

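Interferon-stimulated genes stood lower in F0_Dep than in F0_Ctl in 24 of 25 members with a median of -0.72, none past the threshold, with a camera adjusted p = 5.02e-05 and an adjusted p = 0.726 with an estimated correlation; the median was -0.298 without F0_Ctl 3. Oligodendrocyte and myelin genes stood lower in 19 of 20 with a median of -0.56, an adjusted p = 0.00082 and an adjusted p = 0.763 with an estimated correlation, and their level ran from -0.83 in F0_Ctl 1 to 0.49 in F0_Ctl 3, without which the list had a median of -0.212 and missed the threshold with an adjusted p = 0.214. Vessel markers stood lower in 16 of 20 with a median of -0.37, an adjusted p = 0.000135 and an adjusted p = 0.726 with an estimated correlation. CA2 and CA3 markers stood higher in 14 of 14 with a median of 0.53, an adjusted p = 0.00157 and an adjusted p = 0.763 with an estimated correlation, and missed the threshold without F0_Ctl 1 (median 0.199, adjusted p = 0.0972), without F0_Ctl 2 (median 0.213, adjusted p = 0.0644) and in FPKM (adjusted p = 0.083); without F0_Ctl 3 the median was 1.13. CA1 markers had a median of -0.57 and did not pass, except without F0_Ctl 3 as lower (median -1.03, adjusted p = 1.89e-06). The CA1 level differed widely within F0_Ctl, with a group mean of 0.149 ± 1.35 (SD, n = 3).

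In F1_Dep against F1_Ctl, meningeal fibroblast markers stood lower in 14 of 16 with a median of -0.50, an adjusted p = 0.00603 and an adjusted p = 0.598 with an estimated correlation. They missed the threshold without F1_Ctl 3 (median -0.208, adjusted p = 0.199) and F1_Dep 1 (median -0.283, adjusted p = 0.0833), and stood higher without F0_Ctl 3, F1_Ctl 3 and F1_Dep 1 together (adjusted p = 0.495), a choice made after seeing the data. Thalamus markers stood lower in 12 of 12 with a median of -0.59, or -0.313 without F1_Ctl 2, an adjusted p = 0.0097 and an adjusted p = 0.598 with an estimated correlation. Adult neurogenesis markers stood lower in 14 of 17 with a median of -0.34, an adjusted p = 0.00523 and an adjusted p = 0.526 with an estimated correlation, and missed the threshold without F1_Ctl 1 (adjusted p = 0.0962). Stress-axis receptors and peptides, neurotrophic factors and receptors, GABA synapse genes, inflammatory mediators and interneuron markers passed camera in none of the 6 comparisons; their medians in this one were 0.04, -0.06, 0.01, 0.10 and 0.02, the first opposite in sign to its test. With 1 library left out, GABA synapse genes passed in F0_Dep against F0_Ctl without F0_Ctl 1 (adjusted p = 0.00897) and in F1_Ctl against F0_Ctl without F0_Ctl 3 (adjusted p = 0.00949), interneuron markers in F1_Dep against F0_Ctl without F0_Ctl 1 (adjusted p = 0.0287), and neurotrophic genes in the interaction without F0_Dep 1 (adjusted p = 0.039).

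Microglia marker levels were 0.35, -0.26 and -0.24 in F0_Ctl 1 to 3 and -0.36, 0.56 and 0.45 in F1_Ctl 1 to 3. Levels of mitochondrially encoded genes were 0.38, 0.04 and 0.06, and 0.03, 0.36 and 0.62, in the same libraries. Libraries of one group differed well beyond counting noise, with a chi-square per degree of freedom from 4.86 for F1_Dep 2 and F1_Dep 3 to 84.4 for F1_Ctl 1 and F1_Ctl 3, so no library was counted as a repeat of another.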
